A study of Oryza sativa with 6 samples.

How the data were processed

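RNA was sequenced from root tips of rice seedlings, in 3 wild type (J10) and 3 mutant (lad, also called sr1) samples. Per the labels' protocols, seedlings grew at 25°C, the terminal 0.5 cm of the roots was taken 6 days after sprouting and frozen, total RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit. Groups and replicate numbers were taken from the sample labels, which number the samples of both genotypes 1 to 3.

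The authors deposited 1 table of read counts per gene for the 6 samples, with locus coordinates, gene length and a protein-domain description for part of the genes. Its values are whole numbers with a different total in each column and were taken as counts that had not been normalized; rounded values scaled by size factors would look alike, so the table itself does not show this. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and mm9, which are mouse assemblies and cannot be the source of a table of rice loci. The counting tool, its strand setting, the annotation release and the rice genome build are not given in the sources used here, so coordinates are printed as the deposited table gives them, without a build. Reads from overlapping genes on opposite strands, and from near-identical members of families such as the peroxidases, WRKY factors and glutathione transferases, cannot be told apart where the counting could split or share them, and values of such genes are uncertain to that extent. The table holds 56962 genes, of which 976 have identifiers outside the locus series and 30530 have at least 1 count. Its gene names repeat the locus identifiers, and the NCBI RefSeq gene table for rice (assembly ASM3414082v1) shares no identifier with them, so genes are named by locus and deposited description. Of the 22624 tested genes, 12255 (54.2%) carry a description. Every column of counts matched 1 sample.

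Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter with the group as its argument, which left 22624, libraries were scaled by TMM (factors from 0.924 to 1.04), and a quasi-likelihood model with genotype as its only term was fitted to all 6 libraries. Tests were two-sided on 4 residual degrees of freedom before moderation, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common biological coefficient of variation was 0.165. Fold changes are log2, mutant minus wild type, with standard errors taken as the absolute fold change over the square root of the quasi-likelihood F statistic, and levels are TMM-scaled CPM as mean ± SD. The depth was 16405022 to 20693114 counts per library, at which the 10 highest genes took 2.66 to 3.24% of counts. For a gene with 0 counts in a genotype the fold is a lower bound at 3 counts over that genotype, and for 1 to 3 counts it is a ratio with an exact 95% binomial interval; both cover counting error only, and reads without molecular identifiers are not independent molecules.

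Before the data were examined, 27 gene lists were fixed as text patterns on gene descriptions, together with 22 rice locus identifiers of another annotation, of which 0 matched the table. Because the patterns were written for product names and the table gives domain names, several lists matched only part of what their names cover. Each list with 5 or more tested genes was tested with limma 3.58.1 camera on log2 CPM with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted by Benjamini-Hochberg over lists. With an estimated correlation camera also takes its p-values from the 4 residual degrees of freedom, which raises them even where members are not correlated. A further 17 groups defined by domain and 451 families sharing 1 deposited description were tested in the same way; these sets were added after fold changes of lists and families had been seen.

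The genes named were set by a rule fixed before the data were examined: among genes past the threshold with a mean of at least 5 CPM, no overlap between the genotypes and a description that states a product, the 12 with the highest and the 12 with the lowest log2 fold change; and, in each list, up to 2 higher and 2 lower members with the smallest adjusted p and a mean of at least 5 CPM, or, where none passed, the member with the highest mean CPM. The mutated gene and genes listed by identifier were to be named where identifiable, and none was.

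The procedure was tested on simulated counts with the real genes' means and dispersions and the real library sizes, run on 22310 genes for the comparison of mutant with wild type. With edgeR, 66 of 100 genes simulated with a 2-fold change and 91 of 100 with a 4-fold change were recovered, with 15 false calls. No other gene was changed in the simulation, whereas 45.2% of tested genes were called in the data. Adjusted p-values depend on that share, so these recoveries are not those of the real comparison. On 22624 genes, camera with the preset correlation called 2 of 200 unshifted sets, and with the estimated correlation 1 of 200. Genes were simulated independently and these sets were random, so the simulation held no inter-gene correlation. It cannot show how often camera with the preset correlation calls correlated sets falsely. In the real data the estimated correlation reached 0.931, for cytosolic ribosomal proteins. The alternatives tried were DESeq2 1.42.0, limma voom, edgeR's older robust fit, RLE and upper-quartile factors, library totals alone, factors without the 10 highest genes, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, a threshold of 0.01, and leaving out each replicate; a gene length correction and limma-trend were added after the data were seen.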

Results

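Messenger RNA levels were measured by RNA sequencing in the root tips of rice (Oryza sativa) seedlings grown at 25°C, in 3 libraries from the wild type J10 and 3 from the mutant lad, which the labels also call sr1. Each library came from the terminal 0.5 cm of roots taken 6 days after sprouting. The series title ties the mutant to cell division and to the development of tracheary elements, the water-conducting cells of the xylem. The comparison of the mutant with the wild type asks which transcripts differ in level between these root tips. Gene counts summed to 19242573, 20693114 and 19030866 in wild type replicates 1, 2 and 3, and to 17762603, 16405022 and 18816338 in mutant replicates 1, 2 and 3. Counts above 0 were found for 25401 to 25728 genes in the wild type libraries and for 26920 to 27553 in the mutant libraries. The 6 libraries separated by genotype along the first principal component of log2 CPM (counts scaled to library size), which held 82.4% of the variance, against 6.8% for the second. Spearman correlations across genes were 0.982 to 0.991 within a genotype and 0.885 to 0.925 between genotypes. Every pair of libraries of a genotype differed by more than counting noise (chi-square per degree of freedom from 9.03), so all 6 were kept as separate samples. The labels do not say which locus is mutated in lad, so no locus was examined for that purpose.

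In the mutant root tips, 21 of 35 tested DNA replication genes fell and 1 rose, and all 8 listed cytosolic ribosomal protein genes fell. Of 76 genes with a WRKY domain, a class of transcription factors, 54 rose and 5 fell, and 9 of 11 lipoxygenase genes rose. Of 115 haem peroxidase genes 34 rose and 42 fell. The replication clamp PCNA (LOC_Os02g56130) fell from 191 ± 13.4 to 113 ± 4.53 CPM, and the WRKY gene LOC_Os09g25060 rose from 1.6 ± 0.406 to 102 ± 9.8 CPM (mean ± SD, n = 3 libraries per genotype, here and for every CPM value that follows). Of 22624 genes tested, 10229 (45.2%) changed at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), with 5644 higher and 4585 lower in the mutant. The balance depended on the scaling: 55.2% of the changed genes were higher here, against 49.3% of 10511 with upper-quartile factors, which turns the majority to lower, and 63.1% of 9863 with library totals. At 2-fold or more, with TMM factors, 3444 genes were higher and 1070 lower, and at 8-fold or more 1127 were higher and 39 lower. The 3 values of one genotype lay entirely above or below those of the other for 12850 genes (56.8%), where chance alone gives 10%.

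The described genes with the largest increases were nearly silent in the wild type. LOC_Os01g73250, an ABA/WDS induced protein gene (chromosome 1, 42460555 to 42462334), had 0 counts in all 3 wild type libraries and 12.5 ± 8.11 CPM in the mutant, which is at least 246-fold higher when the wild type is set to a floor of 3 counts over the group. LOC_Os11g47630, a C2H2 zinc finger gene (chromosome 11, 28766092 to 28766937), had 1 wild type count and 30.9 ± 12.3 CPM in the mutant, a ratio of 1800 with a 95% counting interval from 322 to 71000. That count lay in wild type replicate 1, without which the wild type stood at 0 and the gene was at least 395-fold higher. LOC_Os01g71350, of glycoside hydrolase family 17, which includes beta-1,3-glucanases (chromosome 1, 41349731 to 41351148), had 3 wild type counts and 49.9 ± 8.34 CPM in the mutant, a ratio of 947 (324 to 4600). All 3 counts lay in wild type replicate 3, without which the wild type stood at 0 and the gene was at least 640-fold higher. The terpene synthase gene LOC_Os03g24690 reached 15.7 ± 7.13 CPM in the mutant from 1 wild type count, a ratio of 914 (164 to 36200), and without wild type replicate 2, which held that count, it was at least 203-fold higher. The armadillo-fold gene LOC_Os01g33869 reached 21.3 ± 6.12 CPM with a ratio of 410 (140 to 1990), and the oxoglutarate/iron-dependent dioxygenase gene LOC_Os04g49210 reached 18.8 ± 5.49 CPM with a ratio of 352 (120 to 1710). LOC_Os11g37940, with the barwin domain found in a class of pathogenesis-related proteins, reached 10.4 ± 1.23 CPM with a ratio of 298 (82.1 to 2470). LOC_Os03g52180, a reductase gene for 4-hydroxy-3-methylbut-2-enyl diphosphate, the last step of the plastid route to isoprenoid precursors, reached 11.6 ± 1.97 CPM with a ratio of 221 (75.2 to 1070). With so few wild type counts, leaving out 1 wild type library moved each of these 8 folds by over 1.5 times, and no mutant library did. Where the wild type library left out held 0 counts of the gene, the fold fell only because less wild type depth remained. Such a move says nothing about the expression of the gene. Without replicate 1 the bound for LOC_Os01g73250 was 162, and the ratio was 625 (213 to 3030) for LOC_Os01g71350, 603 (108 to 23800) for LOC_Os03g24690, 232 (79.2 to 1130) for LOC_Os04g49210, 196 (54.1 to 1630) for LOC_Os11g37940 and 146 (49.6 to 708) for LOC_Os03g52180. Without replicate 2 the bound for LOC_Os01g73250 was 163, and the ratio was 1190 (214 to 47200) for LOC_Os11g47630, 630 (215 to 3060) for LOC_Os01g71350, 273 (93.1 to 1320) for LOC_Os01g33869, 703 (126 to 27800) for LOC_Os04g49210 and 441 (78.8 to 17400) for LOC_Os03g52180. Without replicate 3 the ratio for LOC_Os01g33869 was 831 (149 to 32900). The remaining 4 had more than 3 wild type counts and rose by 7.01 to 8.62 on the log2 scale. The EamA-domain transporter gene LOC_Os06g10750 rose from 0.155 ± 0.177 to 64.7 ± 24.9 CPM, the AAA-type ATPase gene LOC_Os01g19260 from 0.385 ± 0.347 to 54.5 ± 19.8, the transferase gene LOC_Os11g13970 from 0.125 ± 0.136 to 17.4 ± 5.26, and the NAC transcription factor gene LOC_Os03g42630 from 0.106 ± 0.105 to 14.4 ± 7.91. Adjusted p-values for these 12 genes lay between 1.41e-07 and 9.84e-05 (edgeR quasi-likelihood, Benjamini-Hochberg).

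Of the 12 described genes with the largest decreases, 6 carry the description haem peroxidase, a domain name that does not by itself place their products in the cell wall. LOC_Os03g22010 (chromosome 3, 12611811 to 12617166) fell from 11.3 ± 0.791 to 0.618 ± 0.448 CPM, a log2 change of -4.18 ± 0.37 (SE). LOC_Os10g39160 (chromosome 10, 20895706 to 20896832) fell from 12.1 ± 3.19 to 1.29 ± 0.595 CPM (-3.24 ± 0.33), and LOC_Os07g44460 (chromosome 7, 26557312 to 26558334) from 17.9 ± 4.66 to 2.35 ± 0.252 CPM (-2.92 ± 0.24). The other peroxidase genes were LOC_Os01g18970, with a log2 change of -2.80, LOC_Os05g04440, with -2.75, and LOC_Os07g31610, with -2.44. The SWEET sugar transporter gene LOC_Os01g65880 fell from 62.8 ± 20.8 to 8.3 ± 3.05 CPM (-2.92 ± 0.29), and LOC_Os06g48200, of glycoside hydrolase family 16, which includes xyloglucan-modifying enzymes, from 15.6 ± 3.87 to 2.51 ± 0.468 CPM (-2.64 ± 0.25). The universal stress protein gene LOC_Os02g53320 fell from 56.8 ± 12.1 to 9.36 ± 2.23 CPM. It overlaps LOC_Os02g53330 on the opposite strand, and its value is uncertain because the strand setting of the counting is not given in the sources used here. The ribonuclease H-like gene LOC_Os03g36550 had a log2 change of -2.53, the protein kinase gene LOC_Os04g38910 of -2.40, and the heavy metal-associated domain gene LOC_Os04g52530 of -2.35. Adjusted p-values for these 12 genes lay between 2.98e-06 and 0.000164 (edgeR quasi-likelihood, Benjamini-Hochberg). Among the 24 genes that would rank highest and lowest without the need for a description, 14 carry none; LOC_Os11g45990 (0 wild type counts and 58.9 ± 9.9 CPM in the mutant) and LOC_Os03g02050 (from 13.3 ± 1.57 to 0.381 ± 0.189 CPM) are examples.

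**Figure D1:**
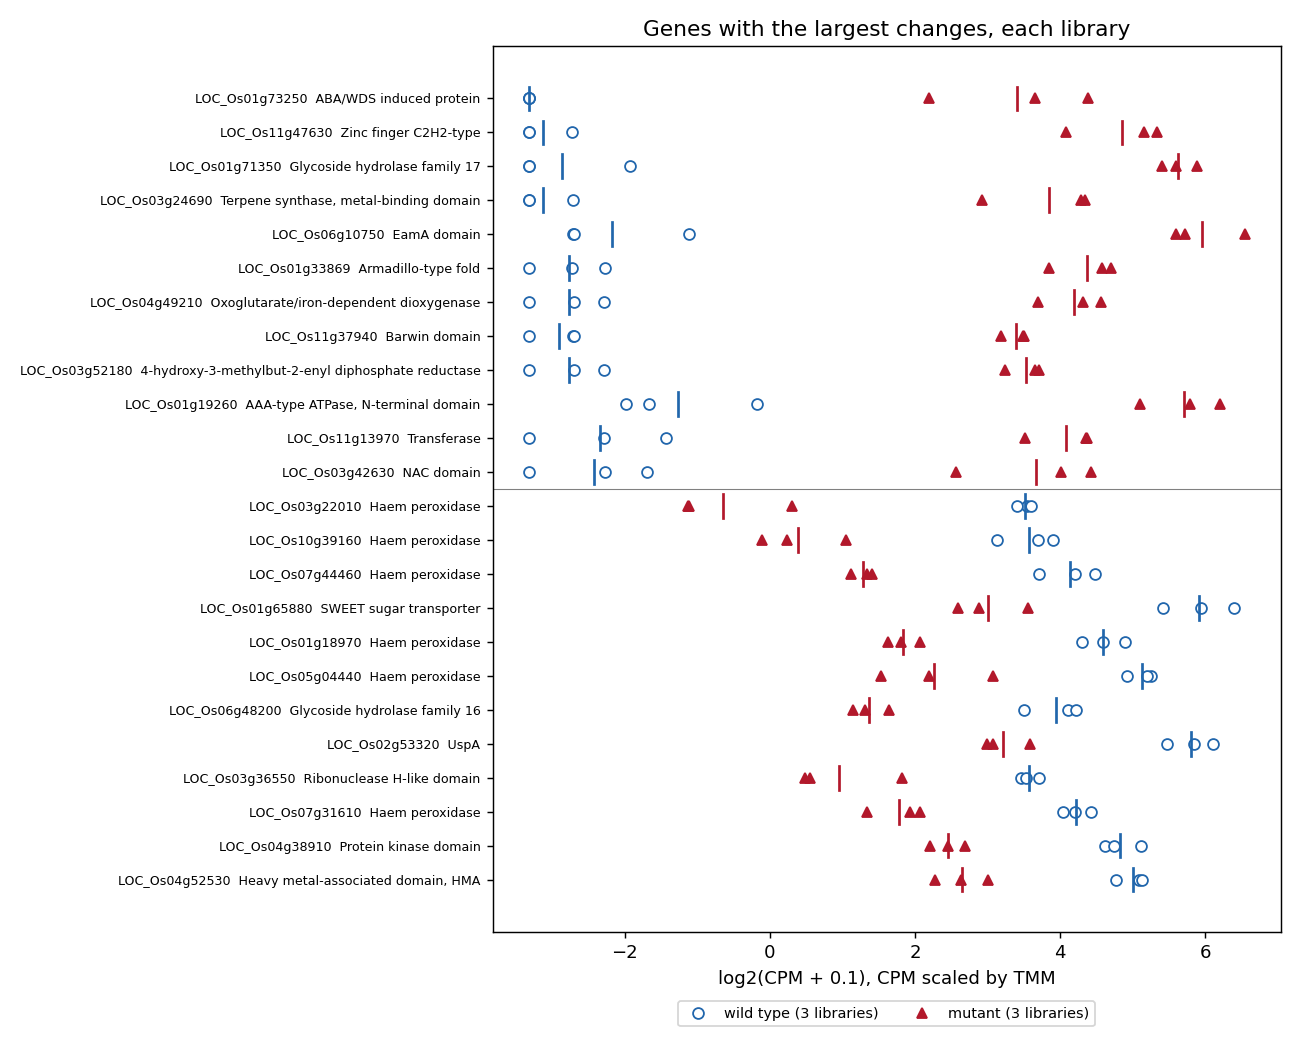
Expression in each of the 6 libraries, as log2 of TMM-scaled CPM plus 0.1, for the 12 described genes with the largest increases (above the line) and the 12 with the largest decreases (below it). Open circles are the 3 wild type libraries, filled triangles the 3 mutant libraries and vertical bars the means of the plotted values; the 2 genotypes do not overlap for any of the 24 genes.

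Of 35 tested DNA replication genes, 21 fell and 1 rose, with a median log2 change of -0.46 (adjusted p = 0.000129, camera with a preset correlation of 0.01; adjusted p = 0.257 with an estimated correlation). PCNA, the sliding clamp that holds DNA polymerase on its template, had a log2 change of -0.75 ± 0.10, and LOC_Os06g07210, the large subunit of ribonucleotide reductase, which makes deoxyribonucleotides, fell from 124 ± 6.42 to 66.3 ± 11.8 CPM. The exception was LOC_Os03g55200, subunit 5 of the origin recognition complex, which rose from 7.39 ± 1.07 to 21.6 ± 8.15 CPM. Of 30 genes in the list of cyclins and mitotic machinery, which by the deposited descriptions holds kinetochore, centromere, condensin, checkpoint and TPX2 proteins and no cyclins, 15 fell, 1 rose and 14 did not pass, with a median of -0.37 (camera, adjusted p = 0.000759; adjusted p = 0.257 with an estimated correlation). Of 7 genes described by a TPX2 C-terminal domain 5 fell, a description that does not by itself tie them to the spindle. Among them LOC_Os11g38010 and LOC_Os02g10690 fell from 96.8 ± 1.82 to 37.6 ± 4.32 CPM and from 59.8 ± 2.08 to 36.8 ± 2.5 CPM. Of 2 genes with a TPX2 central domain and 1 described as targeting protein for Xklp2 (TPX2), 0 passed. LOC_Os09g23370, described as centromere protein V or a formaldehyde-activating enzyme, rose from 24.2 ± 2.73 to 44.4 ± 2.49 CPM. All 8 genes in the list of cytosolic ribosomal proteins fell, with a median of -0.76 (camera, adjusted p = 0.00273; adjusted p = 0.516 with an estimated correlation). Among them LOC_Os08g10608, a 40S protein S11 gene, fell from 252 ± 48.4 to 141 ± 14.8 CPM, and LOC_Os01g67134, of the L5/L18 family, from 254 ± 34.7 to 157 ± 21.9 CPM. Neither of the 2 tested core histone genes passed (edgeR quasi-likelihood). The more abundant one, a feature without a locus identifier, measured 373.5 ± 11.2 CPM in wild type and 425.0 ± 65.9 CPM in the mutant (adjusted p = 0.276, edgeR quasi-likelihood).

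Genes in the lists for cell walls and for peroxidases changed in both directions. Of 11 genes in the list for secondary walls and tracheary elements, 5 rose and 2 fell, with a median of 0.47 (camera, adjusted p = 0.183). Both genes described by a bifunctional nuclease domain rose, a description that does not tie them to xylem, and LOC_Os08g26870 went from 10.1 ± 1.1 to 28.3 ± 5.22 CPM. The other, LOC_Os01g50622, chosen after its values were seen, rose from 0.334 ± 0.0894 to 1.34 ± 0.128 CPM. Of the 9 COBRA genes, which encode anchored proteins needed for cellulose deposition, 3 rose and 2 fell; LOC_Os10g35460 rose from 28.7 ± 1.24 to 64.4 ± 2.11 CPM and LOC_Os07g41320 fell from 53.4 ± 3.63 to 31.8 ± 1.52 CPM. The other lower COBRA gene, LOC_Os03g30250 (17.4 ± 8.46 and 9.53 ± 1.3 CPM), overlaps LOC_Os03g30260 on the opposite strand. Its groups overlapped, and its call (adjusted p = 0.0444) was lost without wild type replicate 1 or 3 or any 1 of the mutant replicates (adjusted p from 0.0717 to 0.139, edgeR quasi-likelihood), with voom (0.103), with library totals (0.0863) and with limma-trend (0.0804). Without wild type replicate 1 its log2 change was -0.50 in place of -0.87. Of 115 haem peroxidase genes, 34 rose and 42 fell, and their median of -0.15 and mean of 0.06 differ in sign (camera, lower, adjusted p = 0.215). LOC_Os05g06970 rose from 2.15 ± 0.537 to 54.5 ± 9.44 CPM and LOC_Os04g55740 from 9.44 ± 0.581 to 60.8 ± 7.38 CPM, while LOC_Os08g42030, like LOC_Os01g18970 above, fell, from 78 ± 2.97 to 28.8 ± 1.59 CPM. Of 39 genes described as cellulose synthases or pectin enzymes, 9 rose and 5 fell. Their median was -0.06, which turned to 0.02 when libraries were scaled by their totals, and their mean was 0.40, of the opposite sign (camera, higher, adjusted p = 0.782). Of 14 genes described as pectinesterases 5 rose and 2 fell. Among them LOC_Os01g57854 and LOC_Os01g65790 rose, from 15.4 ± 5.66 to 53.1 ± 10.2 CPM and from 18.9 ± 4.1 to 43 ± 1.75 CPM. Of 24 genes described as cellulose synthase 4 rose and 3 fell, and this domain description does not show what each product makes. Among the lower ones were LOC_Os08g06380 and LOC_Os07g14850, from 273 ± 65 to 178 ± 7.95 CPM and from 452 ± 59.9 to 352 ± 25.1 CPM. The call for LOC_Os07g14850 was lost without wild type replicate 1 or 3 or any 1 of the mutant replicates (adjusted p from 0.0572 to 0.118, edgeR quasi-likelihood) and with library totals (0.127).

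The list of pathogenesis-related proteins and phytoalexins matched WRKY transcription factors, many of which regulate defence, and Bowman-Birk inhibitors of serine proteases, and no chitinase or phytoalexin enzyme. Of its 85 tested members, 61 rose and 5 fell, with a median of 1.81 (camera, adjusted p = 4.64e-11; adjusted p = 0.257 with an estimated correlation). By description, 54 of 76 WRKY domain genes rose and 5 fell, and 6 of 8 Bowman-Birk genes rose and 0 fell. LOC_Os09g25060 rose by 6.00 ± 0.18 on the log2 scale and LOC_Os05g40070 from 0.881 ± 0.289 to 60.4 ± 3.14 CPM, whereas LOC_Os06g05380 fell from 8.62 ± 0.349 to 5.06 ± 1.25 CPM and LOC_Os02g53100 from 11.8 ± 0.718 to 7.05 ± 2.85 CPM. The call for LOC_Os02g53100 held without mutant replicate 1 and was lost when any 1 of the other replicates was left out (adjusted p from 0.0518 to 0.0823, edgeR quasi-likelihood), with library totals (0.0897) and with the filter of 1 CPM (0.0517). Without mutant replicate 2 its log2 change was -0.45 in place of -0.74. Of 141 genes for glutathione transferases and other redox proteins, 54 rose and 22 fell, with a median of 0.24 (camera, adjusted p = 0.0497; adjusted p = 0.549 with an estimated correlation). Within that list 37 of 58 glutathione transferase genes rose and 6 fell, against 9 higher and 8 lower among 43 thioredoxin-domain genes and 5 higher and 7 lower among 26 glutaredoxins. LOC_Os01g72170 rose from 5.34 ± 0.685 to 121 ± 27.3 CPM and LOC_Os10g38740 from 14.4 ± 1.92 to 204 ± 36.1 CPM, while LOC_Os03g04250 fell from 33.3 ± 1.62 to 11.8 ± 1.68 CPM and LOC_Os01g27390 from 34.9 ± 1.38 to 14.3 ± 2.28 CPM. Of 5 alternative oxidase genes, whose products bypass part of the mitochondrial respiratory chain, 2 rose and 0 fell, with a median of 0.51 (camera, adjusted p = 0.0497; adjusted p = 0.257 with an estimated correlation). LOC_Os04g51150 rose from 7.93 ± 1.04 to 69.3 ± 10.1 CPM. The other, LOC_Os04g51160, chosen after its values were seen, rose from 0.283 ± 0.167 to 8.7 ± 0.79 CPM. Of 105 heat shock and chaperone genes, 15 rose and 30 fell, with a median of -0.14 and a mean of 0.08, which differ in sign (camera, lower, adjusted p = 0.183). The decreases included 13 of 19 Cpn60/TCP-1 chaperonins and 5 of 6 GroES chaperonins, with no increase in either class. The Cpn60 gene LOC_Os06g36700 fell from 612 ± 89 to 322 ± 54.3 CPM and the DnaJ gene LOC_Os03g45344 from 32.5 ± 3.76 to 20.1 ± 0.342 CPM. Of 21 heat shock factors, 7 rose and 2 fell, and LOC_Os09g28354 rose from 4.36 ± 1.16 to 59.6 ± 8.96 CPM. The HSP40/DnaJ gene LOC_Os04g46390 rose from 3.69 ± 0.337 to 13.3 ± 2.44 CPM. Without wild type replicate 1 the chaperone list passed as lower (camera, adjusted p = 0.0429, the lowest of 19 alternatives, which reached 0.753).

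Among hormone lists, 10 of 12 jasmonate genes rose and 0 fell, with a median of 1.43 (camera, adjusted p = 0.000759; adjusted p = 0.257 with an estimated correlation). These were 9 of 11 lipoxygenases, which oxidise fatty acids in the first step towards jasmonate and other oxylipins, and the single tested allene oxide cyclase gene, LOC_Os03g32314, chosen after its values were seen (242 ± 12.2 to 315 ± 19.4 CPM). The lipoxygenase genes LOC_Os03g49350 and LOC_Os03g49260 rose from 20.6 ± 3.49 to 90.2 ± 6.17 CPM and from 18.4 ± 1.67 to 52.9 ± 11.5 CPM. The cytokinin list held 6 cytokinin dehydrogenases, which break the hormone down. Of these 3 rose and 0 fell, with a median of 1.44 (camera, adjusted p = 0.0497; adjusted p = 0.257 with an estimated correlation). LOC_Os01g56810 rose from 10.7 ± 2.44 to 29.4 ± 6.88 CPM and LOC_Os08g35860 from 4.34 ± 1.01 to 11.7 ± 1.36 CPM. The other, LOC_Os01g71310, chosen after its values were seen, rose from 0.37 ± 0.263 to 3.55 ± 0.607 CPM. All 4 tested ethylene insensitive 3-like genes, which encode transcription factors of ethylene signalling, rose, LOC_Os07g48630 from 55.9 ± 12 to 113 ± 17.7 CPM and LOC_Os03g20780 from 15.5 ± 1.9 to 26.1 ± 3.05 CPM. With fewer than 5 members the list was not tested as a set. Of 34 auxin genes, 8 rose and 9 fell, with a median of -0.01 that turned to 0.07 when libraries were scaled by their totals, and a mean of 0.10, which differs from the median in sign (camera, lower, adjusted p = 0.651). The increases were 4 of 12 GH3 genes, whose products join hormones to amino acids, and 4 of 22 auxin response factors, and all 9 decreases were auxin response factors. The GH3 genes LOC_Os01g55940 and LOC_Os07g40290 rose, from 1.85 ± 0.115 to 10.6 ± 2.49 CPM and from 23.4 ± 0.431 to 45 ± 7.95 CPM. The auxin response factor genes LOC_Os06g09660 and LOC_Os05g43920 fell, from 50.7 ± 3.83 to 30.2 ± 3.63 CPM and from 37.5 ± 1.95 to 19.5 ± 4.33 CPM. Of 8 dehydrin and late embryogenesis abundant protein genes, 5 rose and 2 fell, with a median of 0.61 and a mean of 2.30 that includes fitted values of 2 genes with 0 wild type counts (camera, higher, adjusted p = 0.37). Of the 5 dehydrins 3 rose, LOC_Os11g26570, LOC_Os11g26760 and LOC_Os11g26790, which were chosen after their values were seen and had 2, 0 and 0 wild type counts against 67, 61 and 49 in the mutant. The other 2 fell, among them LOC_Os01g50700, also chosen after its values were seen (4.11 ± 0.406 to 1.74 ± 0.337 CPM). The abundant dehydrin gene LOC_Os02g44870 fell from 229 ± 16.3 to 144 ± 39.7 CPM. The LEA5-type genes LOC_Os03g28260 and LOC_Os01g15270 rose from 6.09 ± 0.603 to 10.5 ± 2.89 CPM and from 915 ± 136 to 1228 ± 85.8 CPM. The call for LOC_Os03g28260 was lost without wild type or mutant replicate 3 (adjusted p = 0.0827 and 0.0803, edgeR quasi-likelihood). That for LOC_Os01g15270 was lost without wild type replicate 1 or 3 or any 1 of the mutant replicates (adjusted p from 0.0586 to 0.128, edgeR quasi-likelihood) and with upper-quartile factors (0.06). Without wild type replicate 1 its log2 change was 0.27 in place of 0.42.

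Of 17 genes in the phosphate list, most of them purple acid phosphatases that release phosphate from organic compounds, 5 rose and 3 fell (median 0.30; camera, adjusted p = 0.462; fry, 0.0474). The phosphatase genes LOC_Os12g05510 and LOC_Os12g38760 rose, from 0.874 ± 0.829 to 104 ± 24.4 CPM and from 17.8 ± 5.89 to 70.6 ± 16.9 CPM. LOC_Os03g11530 and LOC_Os04g33530 fell, from 115 ± 14.9 to 56.9 ± 4.64 CPM and from 9.16 ± 0.647 to 2.87 ± 0.257 CPM. Of 26 genes for nitrate and ammonium uptake and assimilation, 11 rose and 3 fell (median 0.34; camera, adjusted p = 0.303; fry, 0.00584). The glutamate synthase gene LOC_Os01g48960 rose from 135 ± 19.6 to 315 ± 41.4 CPM. The asparagine synthase gene LOC_Os03g18130 rose from 3.73 ± 0.746 to 36.2 ± 12.7 CPM and overlaps LOC_Os03g18120 on the opposite strand, which leaves its value uncertain. Of 4 genes described by the glutamine synthetase beta-Grasp domain 2 rose and 2 fell, and the 1 gene described by the catalytic domain rose. The 2 that fell were LOC_Os03g12290 and LOC_Os04g56400, from 52.8 ± 6.72 to 26 ± 2.39 CPM and from 15 ± 4.6 to 6.66 ± 0.653 CPM. Of 14 genes in the hypoxia list, 7 rose and 1 fell, with a median of 0.31. By description 11 carry a sucrose synthase domain and 3 a C-terminal domain of lactate dehydrogenase or glycoside hydrolase family 4. These domain names do not by themselves show what each product does or tie it to hypoxia. The adjusted p of the list was 0.0722 with camera, 0.0429 with camera without wild type replicate 1, and 0.00704 with fry. Over 19 alternatives the adjusted p ran from 0.00704 to 0.516, the highest with an estimated correlation. Among those described as sucrose synthase, LOC_Os03g22120 and LOC_Os06g09450 rose, from 3.64 ± 0.34 to 22.8 ± 1.94 CPM and from 270.1 ± 50.1 to 507 ± 47 CPM. LOC_Os02g58480 fell from 20.7 ± 2.4 to 15.5 ± 1.6 CPM; it overlaps LOC_Os02g58490 on the opposite strand. Its call was lost without wild type replicate 1 or 3 or mutant replicate 1 or 2 (adjusted p from 0.0753 to 0.141, edgeR quasi-likelihood) and with library totals (0.125). Of 11 aquaporin-like water channel genes, 4 rose and 2 fell (median 0.38; camera, adjusted p = 0.195; fry, 0.000998). LOC_Os05g14240 and LOC_Os02g51110 rose, from 19.5 ± 4.93 to 96.9 ± 29.4 CPM and from 179 ± 56.1 to 425 ± 75.7 CPM. LOC_Os03g20410 fell from 17.2 ± 2.02 to 12.3 ± 0.949 CPM, a call lost without replicate 2 or 3 of the wild type or 1 or 3 of the mutant (adjusted p from 0.0586 to 0.0886, edgeR quasi-likelihood) and with library totals (0.0538). The group of major intrinsic proteins, the family name that covers aquaporins, leaned the other way by count, with 3 of 16 higher and 6 lower. Its median was -0.09 and it did not pass (camera, adjusted p = 0.388, and fry, 0.182), so aquaporins as a whole are not shown to be higher. In the iron list, which was too short to test as a set, 1 of 3 nicotianamine synthase genes rose and 0 fell. The one that rose, LOC_Os07g48980, chosen after its values were seen, went from 0.439 ± 0.289 to 6.98 ± 3.33 CPM. The most abundant, LOC_Os03g19427, measured 1472 ± 345 CPM in wild type and 1810 ± 204 CPM in the mutant (adjusted p = 0.201, and 0.0359 without wild type replicate 1, edgeR quasi-likelihood). Of 41 photosynthesis genes matched as markers of shoot tissue, 33 were too low to test, 2 of the other 8 rose and 0 fell (median 0.35; camera, adjusted p = 0.303; fry, 0.000897). The oxygen-evolving enhancer gene LOC_Os04g44190 rose from 4.17 ± 0.611 to 9.56 ± 0.882 CPM. The other higher gene, of the same description, was LOC_Os02g42000, chosen after its values were seen (0.525 ± 0.0397 to 6.57 ± 1.52 CPM).

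**Figure D2:**
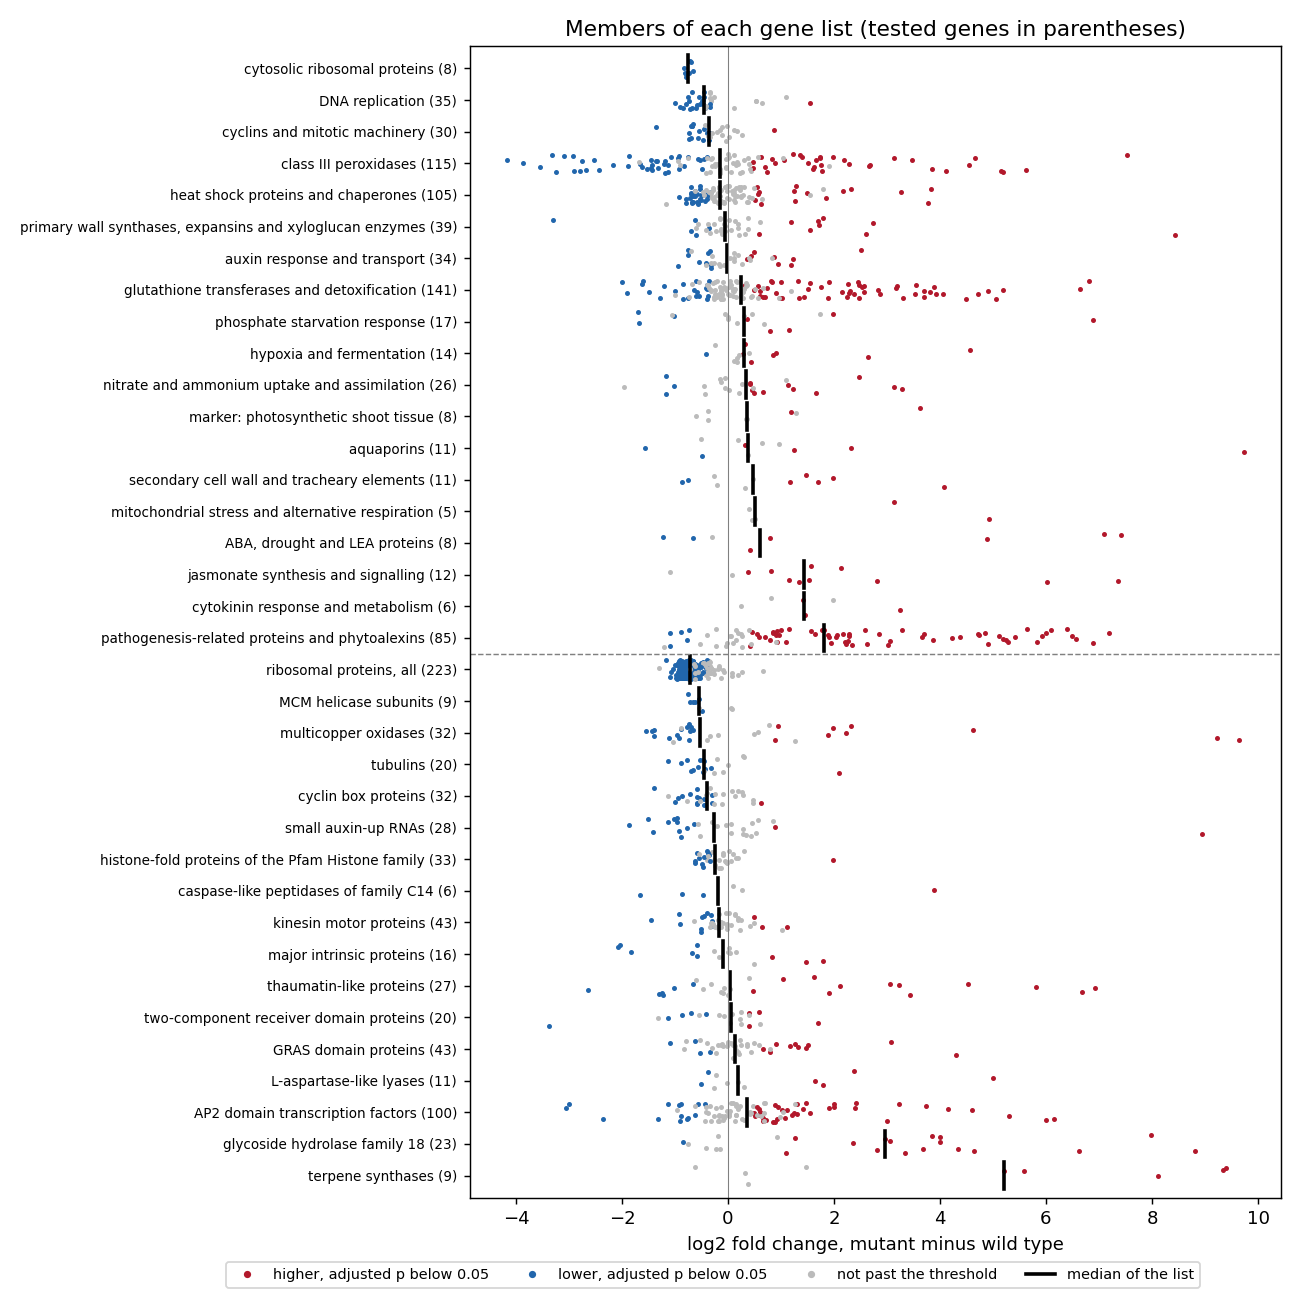
The log2 fold change (mutant minus wild type) of each tested member of the 19 fixed lists with 5 or more tested genes (above the dashed line) and of 17 groups defined by protein domain (below it), with the number of genes in parentheses. Red and blue points are genes higher or lower at an adjusted p below 0.05 (edgeR quasi-likelihood), grey points did not pass, and black bars are medians, which run among the fixed lists from -0.76 for cytosolic ribosomal proteins to 1.81 for the list of pathogenesis-related proteins.

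Of the 27 lists fixed before the data were examined, 19 had 5 or more tested members, 3 had fewer and 5 had none: monolignol synthesis, seed storage, root hair zone, endodermis and stem cell niche. Of these 5, the seed storage list matched 6 genes, which the expression filter removed, and each of the others matched 0 genes of the table. With camera at its preset correlation 5 lists were higher and 3 lower. With an estimated correlation 0 of the 19 passed by camera, 1 had an unadjusted p below 0.05 and the lowest adjusted p was 0.257. That setting also rests on 4 residual degrees of freedom, so a lost call does not by itself show correlated members. The estimates were -0.0843 for cytokinin and -0.0647 for alternative oxidases, below the preset 0.01, and both calls were lost. For the other called lists they ran from 0.0834 to 0.931. The rotation test fry, which does not compare a list with other genes, called 15, adding to those 8 the lists for phosphate, nitrogen, hypoxia, aquaporins and photosynthesis above, that for secondary walls (adjusted p = 0.000897, higher) and that for dehydrins and late embryogenesis proteins (0.00577, higher). For these 7 lists the highest adjusted p over their alternatives lay between 0.516 and 0.666. Adjusted over the list alone, higher and lower members numbered 36 and 44 for peroxidases, 8 and 3 for cellulose synthases and pectin enzymes, 4 and 0 for cytokinin, 62 and 5 for the WRKY and Bowman-Birk list, 5 and 2 for aquaporins and 11 and 4 for nitrogen assimilation. For every other list they were as given over all genes. The labels do not say whether the 3 libraries of a genotype came from separate plants or cultures, so the p-values measure the spread between these samples, which may be technical. The calls for 3 lists depended on the setting. That for cytokinin was lost with DESeq2 (camera, adjusted p = 0.0857), voom (0.0534), library totals (0.0709), no low-count filter (0.162), the filter of 1 CPM (0.0581) and the length correction (0.0534), and without wild type replicate 2 (0.202) or mutant replicate 1 (0.186), 2 (0.199) or 3 (0.175), over a range of 0.00106 to 0.257 in 19 alternatives. That for alternative oxidases was lost with voom (camera, adjusted p = 0.0582), library totals (0.0637) and the replicate block (0.0535), and without wild type replicate 2 (0.0739) or mutant replicate 2 (0.109) or 3 (0.0554), over a range of 0.000897 to 0.257 in 17 alternatives. That for glutathione transferases was lost with library totals (camera, adjusted p = 0.0606), no low-count filter (0.0567), the filter of 1 CPM (0.0621) and the replicate block (0.0679), and without wild type replicate 1 (0.119) or mutant replicate 2 (0.105) or 3 (0.08), over a range of 0.00338 to 0.549 in 19 alternatives.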

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

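The gene length correction, with limma-trend as its baseline, and the domain groups and families were chosen after the data were seen; the other settings were fixed before. The number of changed genes stayed between 7804 and 11191 when single replicates were left out and between 9863 and 10648 in the other settings at the same threshold, against 10229, and no call shared with the main result changed sign in any setting. At an adjusted p below 0.01, genes lower in the mutant numbered 2729 in place of 4585, since a stricter threshold admits fewer. Scaling by library totals moved the median log2 change of all genes from 0.02 to 0.11 and the share of higher genes among those changed from 55.2 to 63.1%; upper-quartile factors gave -0.04 and 49.3%. With the replicate block 10648 genes changed and 6 fixed lists passed, those for alternative oxidases and glutathione transferases being lost (camera, adjusted p = 0.0535 and 0.0679). Deviations of same-numbered samples correlated at 0.057, 0.13 and -0.032, so the numbers are not taken to pair the samples. Of the 8 fixed lists called, 5 passed with library totals and 5 with the filter of 1 CPM, 0 with an estimated correlation and 15 lists with fry, and leaving out replicates gave 5 (without mutant replicate 2, and without mutant replicate 3) to 10. The lists lost other than by the estimated correlation were those for cytokinin, alternative oxidases and glutathione transferases. The alternative oxidase list had under 5 tested genes with the 1 CPM filter and without wild type replicate 3; for the others the cause was not tested. The ethylene list had 5 or more tested genes in 5 settings and passed without wild type replicate 1 (adjusted p = 0.0429), wild type replicate 3 (0.0295) and mutant replicate 1 (0.0346). Lists that had not passed changed direction without passing: dehydrins and late embryogenesis proteins with the 1 CPM filter (adjusted p = 0.567), auxin with fry (0.753), and cellulose synthases and pectin enzymes with the length correction (0.664) and without wild type replicate 2 (0.77), wild type replicate 3 (0.995) or mutant replicate 1 (0.866), over a leave-one-out range of 0.581 to 0.995. Among 1548 pairs of a named gene and a setting, 39 lost the call, 1 gained it and 0 changed sign, in 8 of 86 genes. Families numbered 32 higher and 19 lower, 12 lower with DESeq2, 30 lower with no filter, 181 higher and 73 lower with fry, and 0 with an estimated correlation. The median changed sign under at least 1 of 5 scalings in 4 of 87 lists, groups and families, those for auxin, cellulose synthases and pectin enzymes, thaumatin-like proteins and receiver-domain proteins. At this depth a simulated 2-fold change was recovered in 66 of 100 genes, so a gene that did not pass is not shown to be unchanged. Far fewer genes were changed in the simulation than the 10229 called here, so that share is not the recovery rate of this comparison.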

Other observations

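All the tests introduced in this part were chosen after the results they bear on had been seen, except the test of low-abundance genes. Values of the lists fixed before the data were examined are repeated from above. Grouped by deposited domain, 186 of 223 ribosomal protein genes fell and 0 rose, with a median log2 change of -0.71 (camera, adjusted p = 1.37e-20, and adjusted p = 0.578 with an estimated correlation). This group took ribosomal proteins of all kinds, so it is not limited to those of the cytosol. Lower too were 6 of 9 MCM genes, which encode subunits of the replicative helicase (median -0.55; camera, adjusted p = 0.0203, and adjusted p = 0.197 with an estimated correlation), 12 of 20 tubulins, with 1 higher (-0.45; 0.00465 and 0.197), and 14 of 32 cyclin box proteins, with 1 higher (-0.40; 0.00409 and 0.158). The tubulin gene LOC_Os01g59150 fell from 575 ± 22.7 to 261 ± 20.02 CPM and the cyclin gene LOC_Os09g29100 from 122 ± 12.8 to 61.1 ± 2.26 CPM, with LOC_Os02g55410 of the MCM group going from 91 ± 5.09 to 55.4 ± 2.82 CPM; each was taken as the lower member with the smallest adjusted p. The single higher tubulin gene, LOC_Os03g11970, had a smaller adjusted p than the lower one named (7.69e-06 against 2.2e-05, edgeR quasi-likelihood) and rose from 7.59 ± 1.5 to 32.6 ± 4.83 CPM; it was chosen after its values were seen. Of 33 histone-fold proteins 11 fell and 1 rose (median -0.25; camera, adjusted p = 0.0393, and adjusted p = 0.61 with an estimated correlation). That call was also lost without wild type replicate 2 (0.135), without mutant replicate 3 (0.094), with library totals (0.0636), with the 1 CPM filter (0.0501), with the length correction (0.415) and with fry (0.253), over a range of 0.00126 to 0.61 in 19 alternatives. Kinesin motor genes, with 12 of 43 lower, 3 higher and 28 not passing, did not pass as a group (camera, adjusted p = 0.0617; adjusted p = 0.61 with an estimated correlation, the highest of 19 alternatives). They passed in 9 of these: with DESeq2 (0.0451), voom (0.0433), the older robust fit (0.0463), upper-quartile factors (0.0472), no low-count filter (0.0151), the length correction (0.00388) and fry (0.0396), and without wild type replicate 2 (0.0334) or mutant replicate 1 (0.0167). The kinesin gene LOC_Os03g18980 fell from 230.2 ± 25.7 to 83.6 ± 5.84 CPM. Of 22 genes of glycoside hydrolase family 16, 12 fell and 1 rose (median -0.73; camera, adjusted p = 0.00487, and adjusted p = 0.853 with an estimated correlation).

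Of 23 genes of glycoside hydrolase family 18, which includes chitinases, 16 rose and 1 fell, with a median of 2.96 (camera, adjusted p = 0.000159; adjusted p = 0.155 with an estimated correlation), and LOC_Os05g15770 rose from 18.5 ± 3.94 to 267 ± 9.15 CPM. Of 9 terpene synthases 5 rose and 0 fell, with a median of 5.21, or 5.12 with genes at 0 in a genotype set to their bound (camera, adjusted p = 0.00465; adjusted p = 0.158 with an estimated correlation). Among 451 families, 32 were higher and 19 lower with the preset correlation and 0 with an estimated one, where 15 had an unadjusted p below 0.05 and the lowest adjusted p was 0.853 (camera); fry called 254. Cytochrome P450 genes had 79 of 147 higher and 21 lower, NB-ARC genes, many of which encode immune receptors, 127 of 288 higher and 17 lower, NAC transcription factors 38 of 76 higher and 5 lower and calmodulin-binding protein 60 genes 16 of 21 higher and 0 lower (camera, adjusted p = 0.000289, 0.000111, 0.00066 and 2.66e-05; adjusted p = 0.853 for each with an estimated correlation). The member with the smallest adjusted p was LOC_Os09g26960 among P450 genes, which rose from 22.6 ± 4.41 to 793 ± 229 CPM, and LOC_Os11g16530 among NB-ARC genes, which rose from 16.2 ± 5.23 to 262 ± 40.1 CPM. Multicopper oxidases, the class of laccases, went both ways, with 9 of 32 higher and 14 lower, a median of -0.53 and a mean of 0.63, which differ in sign (camera, lower, adjusted p = 0.179). Of 28 small auxin-up RNA genes 11 fell and 2 rose (camera, adjusted p = 0.121; fry, 0.00586, the lowest of 19 alternatives, which reached 0.353). Of 100 AP2 factors 37 rose and 14 fell (camera, adjusted p = 0.0794; adjusted p = 0.61 with an estimated correlation, the highest of 19 alternatives). They passed in 6 of these: with no low-count filter (0.049), the length correction (0.032) and fry (0.0221), and without wild type replicate 1 (0.0347), wild type replicate 3 (0.0444) or mutant replicate 1 (0.0257). The remaining groups did not pass either. Among them 12 of 27 thaumatin-like genes rose and 6 fell, 3 of 16 major intrinsic proteins rose and 6 fell, 10 of 43 GRAS genes rose and 4 fell, 4 of 11 L-aspartase-like lyases rose and 2 fell, 1 of 6 C14 peptidases rose and 3 fell, and 4 of 20 receiver-domain genes rose and 5 fell. The lyases passed as higher with DESeq2 (camera, adjusted p = 0.0259) and fry (0.0101), and fry also called the thaumatin-like (0.00586) and GRAS genes (0.00743) higher. The highest adjusted p over the alternatives was 0.61, 0.61 and 0.615 for these groups in turn. The median and the mean differed in sign for the C14 peptidases (-0.19 and 0.21) and the receiver-domain genes (0.05 and -0.18, with a median of -0.01 under upper-quartile factors).

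The most abundant gene of the table, LOC_Os09g31080, carries no description and fell from 7956 ± 21.2 to 3056 ± 359 CPM, a log2 change of -1.38 ± 0.16; it was chosen after its values were seen. Haem peroxidases changed in 66.1% of 115 genes, above the 37.4 to 54.8% that spanned the central 95% of random gene groups of the same abundance, with 14 genes at least 4-fold higher and 14 at least 4-fold lower. Of 744 tested genes with identifiers outside the locus series, 30% changed, against 45.7% of the others (Fisher's exact test across genes, which are not independent replicates, p = 7.55e-18).

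Regrouping the 6 libraries into 3 and 3 gave as many changed genes in 1 of the 10 possible splits, the real one, with 10229 genes, and 0 in the highest of the other splits (edgeR quasi-likelihood; up to 996 at an unadjusted p below 0.05, 0 with voom and up to 5 with DESeq2). For changes of 2-fold or more the count was again 1 of 10, with 4514 genes in the real split and 0 in the highest other. The splits are too few to give a share under 0.05. Every other split also mixes the genotypes, so a genotype difference adds to the spread within its groups and lowers its count. The counts of the other splits therefore do not show how many genes would be called by chance.

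Genes changed by 2-fold or more were 3.22 times as often higher as lower in the mutant. Library scaling may shift such a balance, and the ratio was at its lowest 2.63 over 5 scalings, with upper-quartile factors. The choice among these scalings therefore does not account for it. They moved the median log2 change of all genes only between -0.0413 and 0.108, so a larger shift common to all genes is not excluded. Genes of low mean abundance over all 6 libraries were not the only source of the balance. Among genes above the median mean CPM 955 were higher and 361 lower, a ratio of 2.65, against 3.51 at or below the median. That mean includes the mutant, so genes nearly silent in the wild type can lie above the median of 15.3 CPM. LOC_Os06g10750, with 0.155 CPM in the wild type and a mean of 32.4, is an example. The split therefore cannot exclude genes of low wild type abundance as the source. A difference between the genotypes themselves stays open as a hypothesis.

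By count, 186 of 223 ribosomal protein genes, 21 of 35 replication genes and 15 of 30 genes in the mitotic list fell. Those 15 include 5 genes with a TPX2 C-terminal domain, a description that does not by itself tie them to the spindle. In the WRKY and Bowman-Birk list 61 of 85 genes rose. Each of these 4 sets lost its call with an estimated correlation (camera, adjusted p = 0.578, 0.257, 0.257 and 0.257). Gene length bias could give such a pattern, since median changes ran from -0.11 to 0.22 across classes of gene length, yet random groups of the same lengths had medians of -0.185 to 0.0711 against -0.711 for ribosomal proteins, and of -0.188 to 0.162 against 1.81 for the WRKY and Bowman-Birk list. A different make-up of the fixed-length root tip is a candidate explanation, because a piece of 0.5 cm from a shorter meristem could hold more mature tissue. It cannot be told apart from a change within cells here, because the patterns and identifiers of the 3 lists of root zone markers matched 0 genes of the table. Markers of these zones were therefore not examined, which does not mean that they were absent or low. Either route remains a hypothesis.

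Near-silent genes of the wild type were expressed in the mutant more often than the reverse: 179 changed genes had a mean below 0.1 CPM in the wild type and at least 2 CPM in the mutant, and 2 genes, neither with a description, the opposite. Photosynthetic shoot tissue in the mutant samples could bring in foreign transcripts, but of 41 genes matched as photosynthetic, tested or not, only 3 (7.32%) gained 2 CPM or more and 37 stayed below 2 CPM in the mutant, which argues against it. The 8 tested ones had a median log2 change of 0.35, with the 2 oxygen-evolving enhancer genes LOC_Os02g42000, chosen after its values were seen, and LOC_Os04g44190 higher by 3.63 and 1.20 and the list called higher by fry (adjusted p = 0.000897). A few chromosome segments that differ between the lines might also carry such genes, but the 10 fullest bins of 1 Mb held 17.3% of them, against 12.8 to 18.4% for random tested genes, and they lay on 12 chromosomes with at most 25 on one. Reads shared between near-identical genes were not tested, so a biological origin stays a hypothesis.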
